A study of Rattus norvegicus with 38 samples.

How the data were processed

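Brain tissue of newborn Sprague-Dawley rats was profiled in 20 RNA libraries and 18 methylation libraries. Groups, sexes and numbers were taken from the sample labels. The RNA libraries formed 4 groups of 5, and the methylation libraries formed groups of 5 air males, 5 e-cigarette males, 3 air females and 5 e-cigarette females. Per the labels' protocols, DNA and RNA were taken from the tissue with an AllPrep kit, RNA libraries were made with a NuGEN Ovation kit, and RRBS libraries were made with a NuGEN Ultralow Methyl-seq kit. The labels did not say which pups shared a litter or dam. The p-values therefore do not separate litter from exposure. They measure the spread between these libraries, except that those of single CpGs and tiles rest largely on a spread shared across CpGs or tiles.

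The RNA files held whole-number counts per Ensembl rat gene ID, deposited without normalization. Per the submitters' processing notes, the tools were FastQC, Trimmomatic 0.3.7, kallisto 0.44.0, DESeq2 1.38.0 and Trim Galore 0.4.5, with no role given for any of them. Which tool counted, the strand setting and the rat annotation were not given in the sources used here. If kallisto counted, the values are estimates rounded to whole numbers, and reads shared by near-identical genes were divided between them. The build named in the notes was a human assembly, so the rat build was not given in the sources used here. The methylation files held, per the file headers, the coverage of each cytosine as a read count and the percent of its reads with C (methylated) or T (unmethylated). The deposited rows all had a coverage of 10 or more, and the cytosines of both strands of a CpG stood as separate rows. The aligner and the methylation caller were not given in the sources used here. Methylated reads were recovered as coverage times percent, which gave whole numbers for 100% of the rows within the rounding of the files.

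Gene IDs were used as the files give them. The files did not pair the IDs with symbols, and 0 of the 15088 tested IDs matched the reference gene table of 47357 genes, which carried 0 Ensembl IDs. CpG positions exceeded the last gene of that table (assembly GRCr8) on 15 of 22 chromosomes, so its coordinates were not used and no CpG was assigned to a gene. The gene lists, the cell type marker lists and the comparison of promoter methylation with RNA, which were planned, need symbols or gene positions and were not run. Methylation outside CpGs was not analysed here.

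The comparisons, their main tests and most alternatives were set before the data were examined. RNA counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, trimmed mean of M-values scaling, genes kept by the tool's own expression filter). All 20 libraries entered a single fit with 4 group means, and 15088 of 32883 gene IDs were tested. Contrasts were e-cigarette against air in males, in females and averaged over both sexes, the difference between the sexes in that effect, and males against females in air. Calls used a Benjamini-Hochberg adjusted p of 0.05. Principal components used log2 CPM (counts per 1000000 library counts) with a prior count of 2. The rule for named genes asked for more genes than could be printed without symbols, so at most the 2 highest and the 2 lowest log2 fold changes per comparison are named, among called IDs with a mean of at least 1 CPM. This narrower rule was set after the data were examined.

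Methylation was tested per cytosine with a logistic model of methylated and unmethylated reads. The F test used a quasi-binomial dispersion that was moderated across CpGs with limma 3.58.1 and was not allowed below 1. The shared prior carried 43.7 degrees of freedom in males and 52.5 in females, at a dispersion of 1.06 and 1.09. It therefore outweighed each CpG's own spread between animals, and the p-values of CpGs rest mostly on read counts. A CpG entered where its coverage was at least 10 in every library of the comparison. A call needed an adjusted p of 0.05 and a difference of group means of at least 10 percentage points. The same model was used on reads summed over 1000-bp tiles with at least 3 CpG cytosines, with a minimum difference of 5 points. The named positions were the 3 largest gains and 3 largest losses among CpGs, and up to 5 of each among tiles. The level over all CpGs was the mean over 946215 cytosines covered in all 18 libraries, compared with a two-sided exact permutation test. Tiles were tested for a difference between the sexes in the exposure effect with limma on log2 ratios of methylated to unmethylated reads, with an offset of 1. Positions are 1-based and in the coordinates of the files.

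Both pipelines were tested on simulated data with 200 changed genes, CpGs or tiles per setting. For RNA in males, 42.5% of genes changed 1.25-fold, 70% of genes changed 1.5-fold and 81.5% of genes changed 2-fold were recovered, with 14953, 14953 and 14952 genes in the fits. In females these shares were 37.5%, 72.5% and 90.5%, with 14952, 14946 and 14949 genes. False calls were 6 of 91, 12 of 152 and 12 of 175 in males and 0 of 75, 12 of 157 and 9 of 190 in females. Of 1108515 CpGs in males, differences of 10, 20 and 40 points were recovered in 0.5%, 3.5% and 97% of changed CpGs. Of 1071475 CpGs in females, these shares were 0%, 1% and 89.5%. Differences between 20 and 40 points were not simulated. Over 99285 tiles in males, 17.5%, 93.5% and 100% of the changed tiles were recovered at 10, 20 and 40 points. Over 98271 tiles in females, 10%, 71.5% and 100% were recovered. False calls made up 1.29% of all simulated CpG calls and 4.73% of all simulated tile calls, and 4 of 24 calls in the female tile setting of 10 points. A limit of 0.15 per setting on this share had been set first and was replaced by a pooled limit after that setting had exceeded it. The simulated libraries were independent, with no clusters of animals. All CpGs shared the same dispersion, as did all tiles, and the changed ones had mid-range levels. The false shares therefore do not give the error rate in the real libraries. There, other splits called a median of 47 CpGs in males and 79 in females.

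Alternatives for RNA were DESeq2 1.42.0, its size factors, no low-count filter, another filter, limma's voom, fits to a single sex, the replicate number as a block, and each library left out in turn. Alternatives for methylation were a coverage of 20, a relaxed coverage rule, other minimum differences, an unmoderated dispersion, Fisher's exact test on pooled reads, limma on log2 ratios with and without the replicate block, no sex chromosomes, no CpGs of extreme coverage, other tile definitions and each library left out in turn. Library pairs within RNA groups differed by a chi-square of 3.00 to 10.6 per gene, so none was a copy of another. Each was counted as its own sample, which does not make animals that share a dam independent. Among e-cigarette males, pairs within the clusters described below differed by 3.28 to 5.33 and pairs between them by 7.43 to 10.6. Among e-cigarette females these ranges overlapped. The share of methylated reads on the mitochondrial chromosome, which bounds incomplete conversion and miscalling, was 0.336% to 0.502%. The intervals given for ratios of low counts are 95% intervals and cover counting error only.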

Results

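Newborn Sprague-Dawley rats, an outbred laboratory strain, were studied after their dams had been exposed to e-cigarette aerosol or to air. The question was how exposure before birth relates to DNA methylation and transcript levels in the developing brain. RNA was sequenced from 5 air males, 5 e-cigarette males, 5 air females and 5 e-cigarette females. CpG methylation was measured in 18 libraries by reduced representation bisulfite sequencing (RRBS), which reads cytosines near restriction sites as methylated or unmethylated. These were 5 air males, 5 e-cigarette males, 3 air females and 5 e-cigarette females. Libraries that shared exposure, sex and number were taken to come from the same animal. The RNA libraries held 11821877 to 15135705 counts each, with 17693 to 18280 gene IDs above 0, and the 10 most counted genes took 7.74% to 9.42% of the counts. The RRBS libraries listed 1554424 to 1761709 CpG cytosines each, at a median coverage of 17 to 20 reads. Genes are given by their Ensembl IDs, because the files did not pair the IDs with symbols.

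Methylation at the 4709 most variable autosomal CpG cytosines sorted the 18 libraries into 5 clusters, and 0 of the clusters held both exposures. Air males 2 and 3 clustered with air females 3 and 4, air males 4 and 5 with air female 5, and air male 1 stood alone. E-cigarette males 1, 2 and 3 clustered with females 1, 2 and 3 of that exposure, and males 4 and 5 with females 4 and 5. The clusters joined libraries whose deviations from the mean level correlated above 0.2. These correlations ranged from 0.235 to 0.447 over the 30 pairs within clusters and from -0.281 to 0.00442 over the 123 pairs between them. On the odd-numbered chromosomes alone the lowest within was 0.209 and the highest between 0.116, and on the even-numbered 0.176 and 0.0204. For the animals with both assays, each comparison of exposures below was therefore also a comparison between these clusters.

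**Figure D1:**
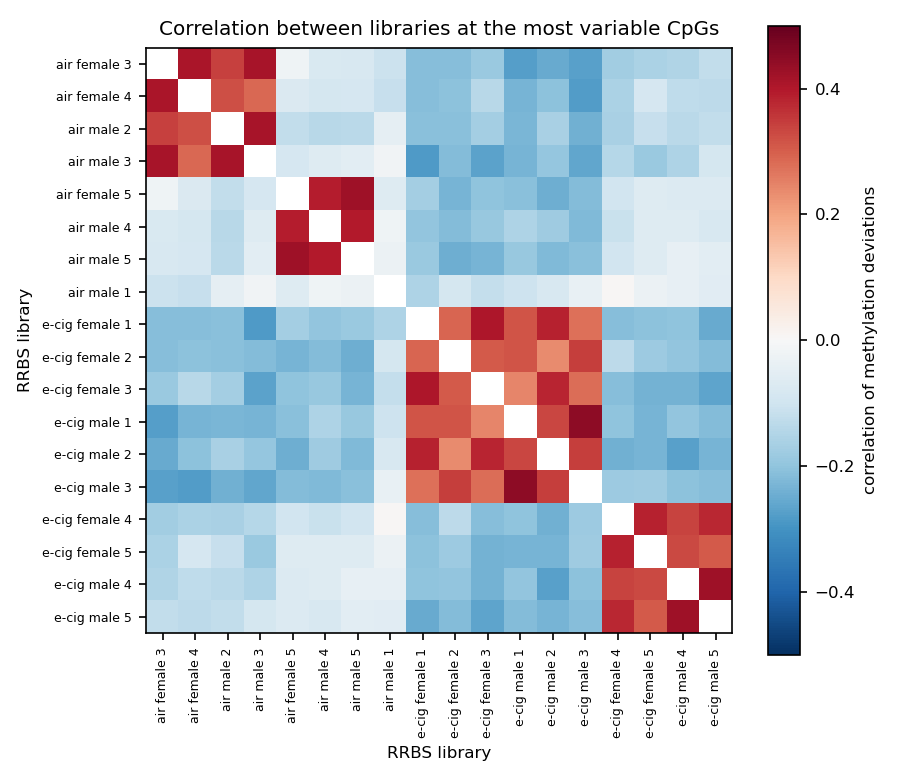
Correlation between each pair of the 18 RRBS libraries, over the 4709 most variable autosomal CpG cytosines, of their deviations from the mean methylation level (color scale; both axes list the libraries, and the diagonal is blank). Pairs within the 5 clusters lie between 0.235 and 0.447, and pairs between clusters lie at or below 0.00442.

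E-cigarette female 5 differed from the other females on the X chromosome. Its ratio of X to autosome coverage was 0.938, against 1.49 to 1.53 in the 7 other female libraries and 0.890 to 0.939 in the 10 male libraries. Its mean methylation over 4427 X cytosines was 45.0%, against 55.3% to 56.4% in the other females and 44.2% to 45.0% in the males. It listed 59 Y cytosines, within the 51 to 71 of the other females and below the 307 to 399 of the males. In RNA it held 4.07 counts per 1000000 library counts (CPM) of ENSRNOG00000051257, the named ID with the largest female excess in air brains, against 35.1 to 48.2 CPM in the 9 other females and at most 1.02 CPM in the males.

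In male brains, 13 gene IDs rose and 18 fell with e-cigarette exposure, of 15088 tested (edgeR quasi-likelihood test, adjusted p threshold 0.05). ENSRNOG00000000499 rose from 0.670 ± 0.530 to 4.02 ± 2.19 CPM (SD, n = 5 per group), a log2 fold change of 2.61 ± 0.54 (SE; edgeR adjusted p = 0.0224). ENSRNOG00000031041 rose from 2.72 ± 0.603 to 6.18 ± 1.4 CPM (edgeR adjusted p = 0.0489). ENSRNOG00000061440 fell from 3.06 ± 2.73 to 0.103 ± 0.101 CPM (edgeR adjusted p = 0.0193). It held 197 counts in air males against 7 in e-cigarette males, a ratio of 29.9. The 95% interval of 14.2 to 75.4 covers counting error only, not the spread between animals. ENSRNOG00000058449 fell from 2.67 ± 0.962 to 0.642 ± 0.436 CPM (edgeR adjusted p = 0.0356). Most of the calls were small, with a median absolute log2 fold change of 0.46, and 8 of the 31 reached 2-fold. At an unadjusted p of 0.05, 1500 IDs passed, against 754 expected by chance. The count fell to 8, 13, 17 and 20 without air male 2, air male 3, e-cigarette male 5 and e-cigarette male 4 in turn. Under limma's voom without a block, 29 IDs were called, but ENSRNOG00000061440 (adjusted p = 0.316), ENSRNOG00000000499 (0.113) and ENSRNOG00000031041 (0.0907) were not among them. DESeq2 called 62 IDs, edgeR without a low-count filter 97 and a fit to the males alone 16. With a random block for the clusters, on the 18 animals with both assays, voom called 15 IDs and none of the 4 named here (adjusted p of 0.172, 0.153, 0.417 and 0.0679 in the order given). The same animals without the block gave 21 IDs and none of the 4 either (0.129, 0.108, 0.352 and 0.0575).

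The levels of ENSRNOG00000061440 were split within the air groups. Air males 1, 4 and 5 held 3.82, 5.46 and 5.67 CPM, and air males 2 and 3 held 0.161 and 0.20 CPM. Air females 2, 3 and 5 held 3.09 to 3.38 CPM, and air females 1 and 4 held 0.247 and 0.0710 CPM. The 10 e-cigarette animals held 0 to 0.231 CPM.

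In female brains, 56 gene IDs rose and 55 fell with exposure, and 10 of these 111 reached 2-fold. ENSRNOG00000042547 rose from 0.208 ± 0.0944 to 5.30 ± 4.72 CPM (SD, n = 5 per group), a log2 fold change of 4.60 ± 0.82 (SE; edgeR adjusted p = 0.00675). ENSRNOG00000011672 rose from 0.572 ± 0.223 to 12.6 ± 24.6 CPM (edgeR adjusted p = 0.0102), and e-cigarette female 4 alone held 56.5 CPM. ENSRNOG00000061440 fell here too, from 2.01 ± 1.70 to 0.0131 ± 0.0293 CPM (edgeR adjusted p = 0.00809). It held 137 counts against 1, a ratio of 146 (95% interval 25.7 to 5792, counting error only). ENSRNOG00000053582 fell from 2.07 ± 1.5 to 0.601 ± 0.256 CPM (edgeR adjusted p = 0.0392). The median absolute log2 fold change of the called IDs was 0.36, and 1700 IDs passed an unadjusted p of 0.05, against 754 expected. Without e-cigarette female 4, ENSRNOG00000011672 lost its call (edgeR adjusted p = 0.397), and the count lay between 34 and 68 without any 1 of air females 1 to 4 or e-cigarette females 2 to 5 (62 without female 5) and at 193 without e-cigarette female 1. Under voom without a block, 92 IDs were called, but none of the 4 named here (adjusted p of 0.283, 0.436, 0.149 and 0.223 in the order given). On the 18 animals with both assays, which left out air females 1 and 2, voom called 2 IDs with or without a block for the clusters, and none of these 4. Their log2 fold changes without a block were 3.64, 2.37, -4.60 and -1.08, against 3.49, 2.16, -4.55 and -1.41 in voom on all 20 libraries. DESeq2 called 182 IDs but gave none of these 4 an adjusted p, edgeR without a low-count filter called 205 and a fit to the females alone 245.

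**Figure D2:**
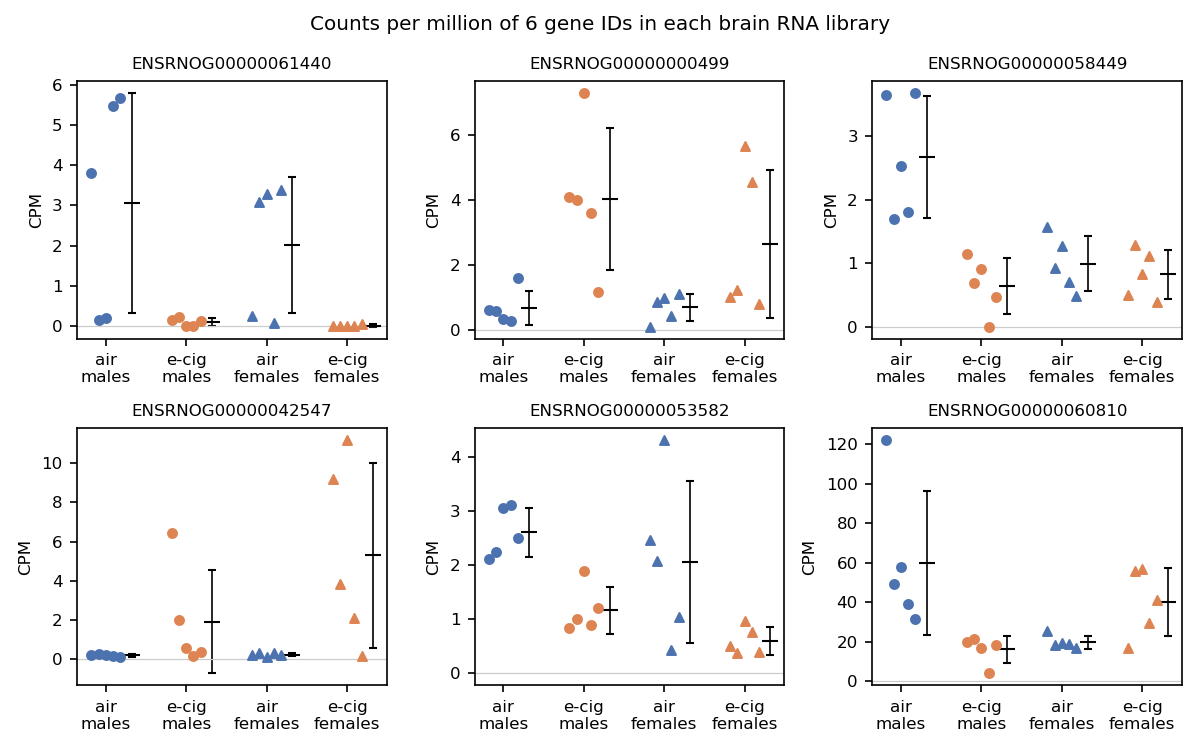
CPM of 6 gene IDs in each RNA library (points; circles, males; triangles, females; blue, air; orange, e-cigarette), with the mean and SD of each group of 5 in black. In each sex 3 of 5 air animals hold at least 3.09 CPM of ENSRNOG00000061440, and the 10 e-cigarette animals hold at most 0.231 CPM.

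Averaged over both sexes, 74 gene IDs rose and 91 fell with exposure. ENSRNOG00000042547 rose by a log2 fold change of 4.01 ± 0.62 (SE; edgeR adjusted p = 0.000785) and ENSRNOG00000000499 by 2.26 ± 0.38 (edgeR adjusted p = 0.00179). For ENSRNOG00000042547 the e-cigarette animals were split: males 4 and 5 and female 5, which share a cluster with female 4, held 0.138, 0.336 and 0.131 CPM, and the 7 others held 0.560 to 11.2 CPM (2.10 in female 4). The 10 air animals held 0.0747 to 0.309 CPM. ENSRNOG00000061440 changed by -5.63 ± 0.77 (edgeR adjusted p = 0.000113). ENSRNOG00000055053 changed by -1.81 ± 0.33 (edgeR adjusted p = 0.00335), from 2.19 ± 0.289 to 0.55 ± 0.212 CPM in males and from 1.58 ± 1.35 to 0.496 ± 0.225 CPM in females (SD, n = 5 per group). Of the 165 called IDs, 17 reached 2-fold, and the median absolute log2 fold change was 0.26. At an unadjusted p of 0.05, 1984 IDs passed, against 754 expected. The count lay between 96 and 109 without any 1 of air males 2 and 3, air females 1 to 3 and e-cigarette female 3, and at 260 without air male 1. Under voom without a block, 160 IDs were called, and ENSRNOG00000042547 was not among them (adjusted p = 0.204). On the 18 animals with both assays, voom called 68 IDs without a block, with ENSRNOG00000055053 among them (adjusted p = 0.0176), and 43 with a random block for the clusters. With that block none of the 4 named here was called (adjusted p of 0.475, 0.181, 0.123 and 0.0509 in the order given), with log2 fold changes of 2.78, 1.91, -4.25 and -1.57, against 2.86, 1.93, -4.17 and -1.58 without it. DESeq2 called 250 IDs but gave none of these 4 an adjusted p, and edgeR without a low-count filter called 309.

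The second principal component of the RNA libraries, with 8.42% of the variance, was positive in the 10 air libraries (3.47 to 15.8) and negative in the 10 e-cigarette libraries (-20.2 to -1.48). The first, with 10.4%, separated the sexes, at -16.0 to -5.87 in males and 8.69 to 13.6 in females. The third, with 7.54%, stood at -22.4 in air male 1, -20.9 and -16.1 in e-cigarette males 4 and 5, and -8.11 and -11.6 in e-cigarette females 4 and 5, which form a cluster with those males. It lay between -0.144 and 12.2 in the 15 other libraries.

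Male and female responses overlapped in 5 called IDs, all changed in the same direction, against 0.114 expected in the same direction of independent lists, although 4 of the 5 clusters held both sexes. Of the 31 male calls, 24 had the same direction in females, and of the 111 female calls, 71 had the same direction in males, as did 54.5% of all tested IDs. Across genes, which are not independent replicates, the log2 fold changes of the sexes correlated at Pearson's r = 0.23 and Spearman's rho = 0.13. The difference between the male and female effects passed the threshold for 6 IDs, all with a lower log2 fold change in males. ENSRNOG00000060810 held 59.9 ± 36.3 CPM in air males and 16.1 ± 6.97 CPM in e-cigarette males, and 19.7 ± 3.29 CPM in air females and 40.01 ± 17.2 CPM in e-cigarette females (SD, n = 5 per group). Its log2 fold changes of -1.90 and 1.03 differed by -2.93 ± 0.43 (SE; edgeR adjusted p = 0.0016). ENSRNOG00000053462 held 204 ± 59.1 and 128 ± 55.1 CPM in air and e-cigarette males and 134 ± 26.7 and 282 ± 102 CPM in the females, a difference of -1.75 ± 0.32 (SE; edgeR adjusted p = 0.026). An unadjusted p of 0.05 was passed by 1262 IDs, against 754 expected. The count was 0 under voom without a block, 37 with DESeq2 and 54 without a low-count filter. It was 46 without e-cigarette female 1, 10 without air male 2, and 1 or 2 without any 1 of air females 1, 2 and 4 and e-cigarette females 2 to 4.

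Between the sexes in air, 10 gene IDs were higher in males and 6 in females. ENSRNOG00000057231 held 60.5 ± 2.12 CPM in males and 0.0777 ± 0.108 CPM in females (edgeR adjusted p = 5.49e-25). Its 3980 counts against 5 gave a ratio of 813 (95% interval 348 to 2504, counting error only). ENSRNOG00000060496 held 30.9 ± 3.58 and 0.0478 ± 0.0728 CPM (edgeR adjusted p = 9.64e-23), with 2017 counts against 3, a ratio of 686 (235 to 3331). ENSRNOG00000051257 held 44.2 ± 3.88 CPM in females and 0.418 ± 0.360 CPM in males (edgeR adjusted p = 9.57e-12). ENSRNOG00000055225 held 3.94 ± 0.621 CPM in females and 0.0775 ± 0.0596 CPM in males (edgeR adjusted p = 5.67e-07; SD, n = 5 per group for these IDs). These levels followed the sex labels in every air library. Under voom without a block, 13 IDs were called, and ENSRNOG00000051257 was not among them (adjusted p = 0.262). The count was 33 without a low-count filter and 6 in voom on the 18 animals with both assays, with or without a block for the clusters. An unadjusted p of 0.05 was passed by 872 IDs, against 754 expected.

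Mean CpG methylation did not differ detectably with exposure in either sex. Over the 946215 cytosines covered in all 18 libraries it was 35.9% ± 0.189 in 5 air males and 35.8% ± 0.0828 in 5 e-cigarette males, a difference of -0.0451 points (two-sided exact permutation p = 0.619). In females it was 36.0% ± 0.276 in 3 air and 36.0% ± 0.0710 in 5 e-cigarette animals (SD), a difference of -0.00500 points (two-sided exact permutation p = 0.982). Single libraries lay between 35.6% and 36.3%. When all reads were pooled, which weights deeply covered CpGs, the female difference was -0.901 points (exact permutation p = 0.0536).

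**Figure D3:**
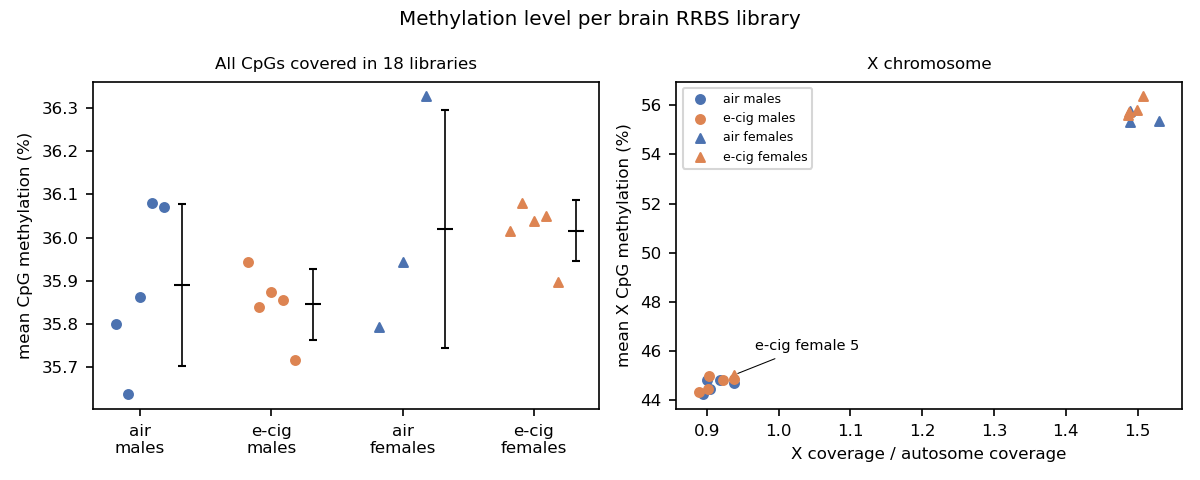
Left, mean CpG methylation in percent of each RRBS library over 946215 cytosines, by group, with the mean and SD in black (axis does not start at 0). Right, mean methylation of 4427 X cytosines against the ratio of X to autosome coverage; e-cigarette female 5 lies at 0.938 and 45.0%, beside the males and apart from the other females at 1.49 to 1.53.

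In males, 207 CpG cytosines gained and 219 lost methylation with exposure, of 1108515 tested, and the median absolute difference was 39.4 points. The largest loss lay at position 14946809 of chromosome 10, from 84.5% ± 4.20 in air to 0% in e-cigarette males (adjusted p = 1.36e-14; coverage 19 to 37 reads). Further losses lay at both strands of the CpG at 15748229 and 15748230 of chromosome 10, from 81.7% ± 25.5 and 80.9% ± 19.4 to 0% in each e-cigarette male. The largest gain lay at 15059889 of chromosome 10, from 8.89% ± 19.9 to 83.9% ± 8.49 (adjusted p = 1.69e-06), where 4 of 5 air males stood at 0% and air male 1 at 44.4%. Gains also lay at 16567660 of chromosome 10, from 0% to 74.7% ± 25.2, and at 23639913 of chromosome 17, from 2.87% ± 4.16 to 74.2% ± 18.2 (SD, n = 5 per group; coverage of at least 10). The adjusted p-values are from the moderated quasi-binomial test across all CpGs with limma, and they do not account for the clusters of libraries. At an unadjusted p of 0.05, 36166 CpGs passed, against 55426 if p-values were uniform. They need not be uniform, since the dispersion was not allowed below 1. Of the CpGs covered in all 18 libraries, 52.6% to 52.8% stood below 10% in each male library. The calls numbered 50 with limma on log2 ratios, 64 at a coverage of 20 and 0 without moderation of the dispersion. Recovery without moderation, which leaves few degrees of freedom per CpG, was not simulated.

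In females, 331 CpG cytosines gained and 491 lost methylation, of 1071475 tested, with a median absolute difference of 37.9 points. The largest loss lay at 103259491 of chromosome 10, from 96.7% ± 5.77 in 3 air females to 13.8% ± 18.7 in 5 e-cigarette females (limma-moderated test, adjusted p = 1.76e-07; coverage 13 to 26). Losses also lay at 83529347 of chromosome 11, from 94.1% ± 5.88 to 13.3% ± 22.9, and at 107145753 of chromosome 14, from 100% to 21.03% ± 29.3. The largest gain lay at 277233975 of chromosome 1, from 12.5% ± 21.7 to 86.2% ± 15.6 (limma-moderated test, adjusted p = 1.79e-06; coverage 15 to 25). Gains also lay at 129156036 of chromosome 6, from 0% to 73.0% ± 21.4, and at 101445628 of chromosome 13, from 5.56% ± 9.62 to 78.4% ± 24.2 (SD). The count was 0 without moderation of the dispersion, 49 with limma on log2 ratios and 186 at a coverage of 20. At an unadjusted p of 0.05, 33628 CpGs passed, against 53574 if p-values were uniform.

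**Figure D4:**
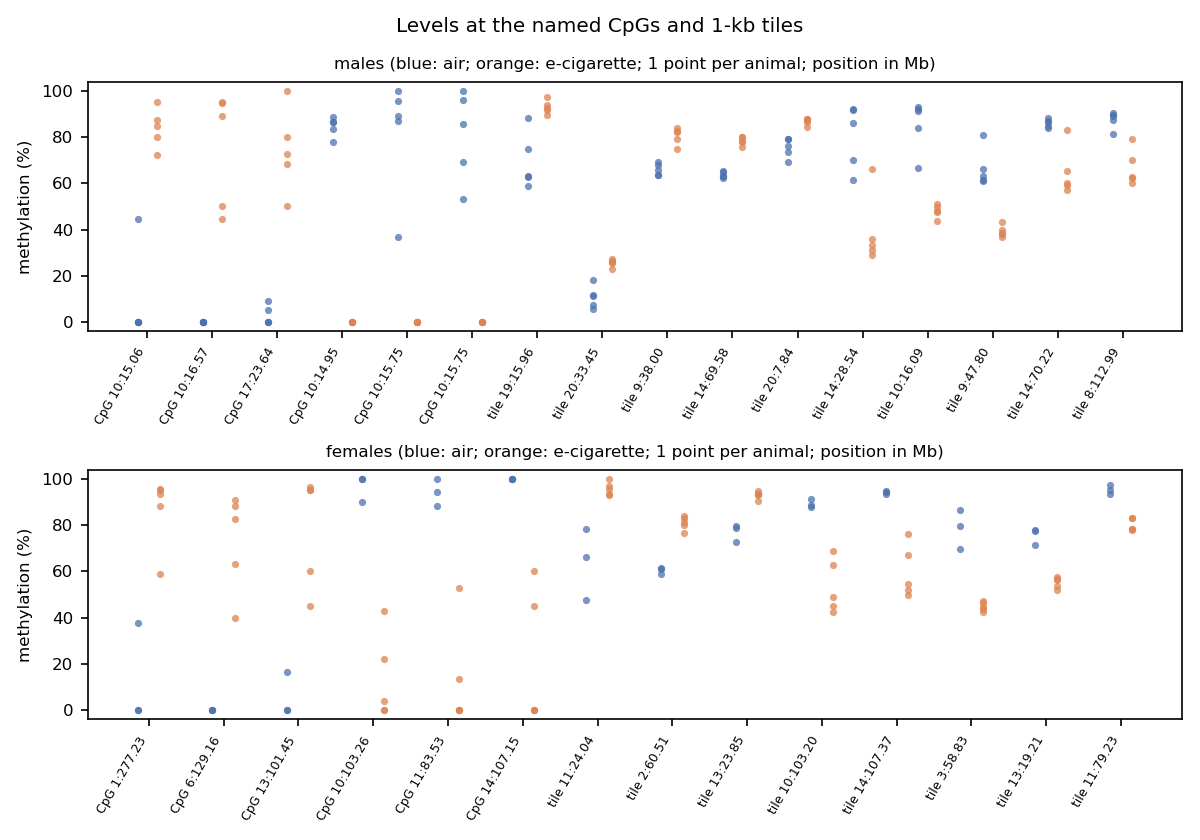
Methylation level in percent of each animal (points; blue, air; orange, e-cigarette) at the named CpGs and 1-kb tiles of males (top) and females (bottom), with chromosome and position in megabases (Mb) on the horizontal axis. Several CpGs step between 0% and high levels, such as position 14946809 of chromosome 10 in males (84.5% to 0%).

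The called CpGs of the sexes overlapped. Of 946215 CpGs tested in both, 151 were called in both and 150 of these changed in the same direction, against 0.155 expected in the same direction of independent lists. Of the 5 clusters, 4 held both sexes. Across all CpGs tested in both, the differences of the sexes correlated at Pearson's r = 0.106 and Spearman's rho = 0.0232. The calls also lay close together. In males 64 of 426 and in females 341 of 822 lay in 1-Mb windows with at least 5 calls, against means of 0.751 and 10.6 in random draws of the tested CpGs. The draws took single cytosines, while the calls covered 385 and 735 CpG dinucleotides. Part of the closeness therefore follows from counting both strands. In females, 101 calls lay in the window from 11000001 to 12000000 of chromosome 1, against at most 10 in a window of the draws. In males, the fullest window ran from 16000001 to 17000000 of chromosome 10 and held 12 calls, against at most 8. It included the named cytosine at 16567660 and the named tile from 16094001. The other named male cytosines of chromosome 10 lay between 14946809 and 15748230. Whether these positions varied together between animals was not tested.

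Over 1-kb tiles, 11 gained and 10 lost methylation in males, of 99285 tested. The largest loss lay in the tile from 28544001 to 28545000 of chromosome 14, from 80.2% ± 13.8 to 39.2% ± 15.4 (SD, n = 5 per group; limma-moderated test, adjusted p = 0.0256). The tile from 16094001 to 16095000 of chromosome 10 fell from 85.3% ± 11.03 to 48.0% ± 2.84, and the tile from 47801001 to 47802000 of chromosome 9 from 66.6% ± 8.30 to 39.3% ± 2.37. The largest gain lay in the tile from 15962001 to 15963000 of chromosome 19, from 69.7% ± 12.1 to 92.9% ± 2.81, and the tile from 69580001 to 69581000 of chromosome 14 rose from 63.8% ± 1.33 to 78.4% ± 1.76. In females, 3 tiles gained and 7 lost, of 98271 tested. The tile from 24042001 to 24043000 of chromosome 11 rose from 64.0% ± 15.3 to 95.7% ± 2.82, and the tile from 60512001 to 60513000 of chromosome 2 from 60.6% ± 1.37 to 81.0% ± 2.89 (SD, n = 3 and 5; limma-moderated test, adjusted p = 0.0164 and 0.00569). The tile from 103200001 to 103201000 of chromosome 10 fell from 89.3% ± 1.85 to 53.7% ± 11.5, and the tile from 107374001 to 107375000 of chromosome 14 from 94.1% ± 0.726 to 59.9% ± 11.2. The sexes shared 0 called tiles, against 0.000993 expected in the same direction of independent lists. Of the calls tested in both sexes, 14 of 19 male and 9 of 10 female tiles had the same direction in the other sex, and across all tiles tested in both the differences correlated at Pearson's r = 0.149. At an unadjusted p of 0.05, 4750 male and 4394 female tiles passed, against 4964 and 4914 if p-values were uniform. The counts were 0 in both sexes without moderation and 1 each with limma on log2 ratios, and the female count rose to 37 without the sex chromosomes. It rose to 46, 39 and 24 without e-cigarette female 5, air female 5 and e-cigarette female 3, and the male count fell to 12, 12 and 13 without air male 2, e-cigarette male 3 and air male 4.

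A difference between males and females in the effect of exposure on tile methylation was called in 0 of 88275 tiles (limma, smallest adjusted p = 0.126). Recovery was not simulated for this test. Within each sex, limma on log2 ratios called fewer tiles than the main test, so the 0 does not show equal effects. An unadjusted p of 0.05 was passed by 4188 tiles, against 4414 expected. Leaving out air male 2 or e-cigarette male 3 gave 1 called tile each.

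In air brains, the sexes differed at 2849 of 1113525 CpG cytosines, 2730 of them lower in males. The X chromosome held 2405 of these, 32.9% of its 7313 tested cytosines, and 2384 were lower in males. The called X cytosines had a mean level of 33.4% in the 3 females and 2.18% in the 5 males. Position 27016207 of the X chromosome stood at 58.2% ± 4.48 in females and 0% in males, and position 18082574 at 58.8% ± 11.8 and 1.54% ± 3.44 (SD; limma-moderated test, adjusted p = 1.14e-07 and 5.12e-06). On the autosomes 443 cytosines were called, 0.0400% of those tested, among them 96813023 of chromosome 9, with 1.75% ± 3.04 in females and 66.0% ± 39.4 in males. Splits of the same libraries that mixed the sexes called up to 1087 CpGs over all chromosomes. A split that kept the clusters whole called 928. The autosomal calls therefore cannot be ascribed to sex. At a coverage of 20 the sexes differed at 198 CpGs.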

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

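Some tests were chosen after the results were seen. These were the other splits for the 1-kb tiles and the splits of the female RNA libraries that kept the known clusters whole. The removal of a random CpG dinucleotide and the tests on the X chromosome of e-cigarette female 5 were others. So were the neighbour ratios of the cytosines called between the sexes.

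In 102 tests, each of 1 measure in 1 group of 5 libraries, 15 values stood far from the others of their group. About 1 test in 20 (5.1) would by chance. The same libraries recur in these tests, which are therefore not independent. E-cigarette female 5 had an X to autosome coverage ratio of 0.938 and an X methylation level of 45.0%, below the other e-cigarette females. Air male 5 held 1.58 CPM of ENSRNOG00000000499, above the other air males, and 56.8 CPM of ENSRNOG00000057231, below them. E-cigarette female 4 held 56.5 CPM of ENSRNOG00000011672, above the others of its group. E-cigarette female 5 held 0.0656 CPM of ENSRNOG00000061440, which was a single count where the others of its group had 0. ENSRNOG00000060810 stood apart at 122 CPM in air male 1, 3.999 CPM in e-cigarette male 4 and 25.3 CPM in air female 1. Air male 1 stood apart at 2 CpGs of chromosome 10, with 44.4% at 15059889 and 37.0% at 15748229. E-cigarette male 3 had 66.3% in the tile from 28544001 of chromosome 14, and air male 2 had 81.0% in the tile from 47801001 of chromosome 9. E-cigarette female 5 had 58.8% at 277233975 of chromosome 1 and 52.9% at 83529347 of chromosome 11.

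The effect of exposure on RNA differed between males and females for 6 gene IDs. The male minus female difference in log2 fold change was -2.93 for ENSRNOG00000060810 and -1.75 for ENSRNOG00000053462. Of 100 splits of the libraries, 2 gave as many as 6 IDs, the real split included, and the highest other gave 47, with its males divided as in the split of the males that called 152 (air males 1 and 2 with e-cigarette males 2, 4 and 5). Such a count points to a structure of the male libraries, whose source was not tested.

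Other splits of the same libraries were compared with each further count. For RNA, 4 of 100 splits of the males gave as many as the real 31 IDs (highest other 152), 1 of 100 in females (real 111, highest other 15), 1 of 100 for the mean of the sexes (real 165, highest other 3) and 1 of 100 for the sexes in air (real 16, highest other 9). For CpGs, 2 of 100 splits of the males (real 426, highest other 485), 2 of 56 of the females (real 822, highest other 833) and 1 of 56 of the sexes in air (real 2849, highest other 1087) gave as many. For tiles, 2 of 100 in males (real 21, highest other 30) and 2 of 56 in females (real 10, highest other 19) gave as many. A random grouping of single libraries could therefore be excluded at 0.05 for these counts. For the RNA of males this holds only by the splits drawn of 126 possible, since a split not drawn called 180. A random grouping was not excluded for the tiles with a different effect in the sexes. There, 100 of 100 splits gave at least the real 0 and the highest gave 2. No split can give fewer than 0, so this comparison decides nothing for those tiles. Of the CpGs called between the sexes in air, 2405 lay on the X chromosome. The 443 autosomal calls lie below the highest other count of 1087, so a random grouping is not excluded for them. The splits mostly cut across the inferred clusters and so exclude a random grouping of single libraries, not a grouping by relatedness. With the clusters kept whole, the RRBS libraries of each sex had 3 splits. These are too few to exclude a random allocation of whole clusters at 0.05 for the CpG and tile counts.

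The CpG and tile differences between exposures were weighed first. Other CpG dinucleotides within 100 bp differed by a median of 0.0197 (males) and 0.0485 (females) of the difference at the called CpG. Around cytosines called between the sexes this ratio was 0.869 on the X chromosome and 0.608 on the autosomes (lower quartile 0.0342). The low ratios of the exposure calls could arise from sequence variants at the called cytosines. A rule set beforehand took the loss of most calls as the mark of a single CpG dinucleotide carrying each tile. That rule was met. Without their most different dinucleotide 0 of 21 male and 0 of 10 female tiles kept their call. Without a random other dinucleotide 17 and 8 did. The median difference fell from 14.6 to 4.26 and from 20.3 to 4.60 points. The question was still left undecided, by a condition on the remaining difference that was not part of the rule. The tiles had been chosen for their difference, 10 and 4 still differed by 5 points, and 19 and 8 kept their direction. Relatedness of the animals may set the counts, since the other splits that kept the clusters whole called 485 and 400 CpGs in males (real 426) and 833 and 494 in females (real 822). An effect of exposure itself stays open and untested, because 0 of 5 clusters held both exposures. The upper quartile of the neighbour ratio was 0.655 in females and 0.0709 in males, so part of the female calls extended over neighbouring CpGs. The dense stretches described below held 84 and 60 of the 822 female calls, and the ratio was not computed without them.

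The RNA differences between exposures were weighed second. In males, relatedness may account for the count of 31, since a split that kept the clusters whole (air males 4 and 5 with e-cigarette males 1 to 3, against the rest) called 180 IDs, although the other such split called 1. A drawn split across the clusters (air males 1 and 2 with e-cigarette males 2, 4 and 5) called 152, and like both of these it put air male 1 with e-cigarette males 4 and 5, which the third component set apart (-22.4 to -16.1, other males 1.22 to 12.2) for a reason not tested. In females the 4 other splits that kept the known clusters whole called at most 1 ID, against 111, which speaks against clusters differing this much in general, but relatedness cannot be told apart from exposure: air females 1 and 2 had no known cluster, and such splits of the males called as few as 1 and as many as 180. An effect of exposure stays open in both sexes, because 0 of 5 clusters held both exposures.

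The X chromosome of e-cigarette female 5 was weighed last. A mislabelled male would bring Y cytosines, and its RRBS library listed 59, against 307 to 399 in males and 51 to 71 in the other females. Low depth would remove autosomal cytosines as well, and it listed 97.2% of the autosomal mean of the other females but 51.3% of their X mean. A single X chromosome in most cells of this animal is a candidate explanation, with an X to autosome coverage ratio of 0.938, within the 0.890 to 0.939 of the males, and the low level of the female-high ENSRNOG00000051257 (4.07 CPM) in its RNA. The design names no group that would test a link to exposure in a single animal, so no biological explanation beyond the karyotype was tested.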

How the results depend on the processing

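The fits on 18 animals with both assays, the libraries left out of the CpG comparison of the sexes and all alternatives for the tiles with a different effect in the sexes were chosen after the data were seen. RNA counts are given for males, females, their mean, the difference between the sexes and the sexes in air, which were 31, 111, 165, 6 and 16. Size factors of another kind, a filter of 1 CPM and, for the sexes in air, DESeq2 kept each count within 1.5-fold, as did voom except for the difference between the sexes. DESeq2 called 62, 182, 250 and 37 in the first 4, and no low-count filter gave 97, 205, 309, 54 and 33. Fits to a single sex called 16 in males and 245 in females. The replicate numbers did not pair the libraries: same-number correlations lay between -0.0500 and 0.101, and the own number correlated best in 0, 2, 2 and 2 of 5 cases. The replicate block changed the difference between the sexes to 2 with a fixed block and to 1 with a random block in voom, where voom without a block gave 0; it moved no other RNA count by over 1.5-fold. A random block for the inferred clusters in voom on 18 animals gave 15, 2, 43, 0 and 6, and the same animals in voom without the block 21, 2, 68, 0 and 6, where voom on all 20 gave 29, 92, 160, 0 and 13. Leaving out each library gave 8 to 33 in males (8, 13, 17 and 20 without air males 2 and 3 and e-cigarette males 5 and 4). It gave 34 to 193 in females (45, 60, 68 and 52 without air females 1 to 4, and 193, 44, 34, 46 and 62 without e-cigarette females 1 to 5). The mean ranged from 96 to 260 (260, 100 and 96 without air males 1 to 3, 101, 105 and 109 without air females 1 to 3, and 97 without e-cigarette female 3). The difference between the sexes ranged from 1 to 46 (46 without e-cigarette female 1, 10 without air male 2, 2 without air female 2, and 1 without air female 1 or 4 or e-cigarette female 2, 3 or 4), and the sexes in air from 11 to 19. The difference in mean CpG methylation passed its threshold under no alternative. It turned from -0.00500 to 0.00330 points in females without the sex chromosomes, and ranged from -0.109 to 0.00231 in males and from -0.120 to 0.148 in females when a library was left out, above 0 without air male 4 or 5 (0.00231 and 0.000223) and without air female 5 or e-cigarette female 5 (0.148 and 0.0249). With same-number differences (replicate block) it was -0.0451 and -0.0259 points. CpG counts of 426 in males and 822 in females became 64 and 186 at a coverage of 20, 0 and 0 with an unmoderated dispersion, 1340 and 1611 with Fisher's exact test on pooled reads, 50 and 49 with limma on log2 ratios, and 38 and 0 with limma and the replicate block. Tile counts of 21 and 10 became 6 and 1 at a coverage of 20, 0 and 0 with an unmoderated dispersion, 1099 and 1190 with Fisher's test, 1 and 1 with limma, 0 and 0 with limma and the replicate block, and 7 and 4 with at least 5 CpGs per tile. Female tiles also rose to 18 under the relaxed coverage rule and to 37 without the sex chromosomes. The relaxed rule for CpGs and male tiles, other minimum differences, tiles of 500 bp and the removal of CpGs of extreme coverage kept the counts within 1.5-fold. Leaving out a library gave 354 to 586 CpGs in males and 673 to 1144 in females, 12 to 22 tiles in males (12, 13 and 12 without air males 2 and 4 and e-cigarette male 3), and 7 to 46 tiles in females (39, 24 and 46 without air female 5 and e-cigarette females 3 and 5). The CpGs differing between the sexes in air numbered 198 at a coverage of 20, and 2510 to 3122 without a library, against 2849. Tiles with a different effect in the sexes stayed at 0 under 5 alternatives, among them the replicate block, and ranged from 0 to 1 when a library was left out (1 without air male 2 or e-cigarette male 3). Named gene IDs kept their call in 308 of 406 refits, named CpGs in 192 of 216 and named tiles in 204 of 340, and 0 changed direction. Except where fewer animals or CpGs entered by construction, the cause was not tested. The gene list, marker list and promoter results and their alternatives were not run. At the depth of these libraries, 3.5% (males) and 1% (females) of simulated differences of 20 points at CpGs of mid-range level were recovered. Depth itself was not varied.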

Other observations

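The regions of dense calls and the correlation of RNA between male and female animals were chosen for testing after the results were seen.

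The female CpG calls were densest in 2 regions, both with lower methylation in e-cigarette females. Between 128816571 and 128818992 of chromosome 2, 60 called CpG cytosines lay in a stretch whose mean level over 163 cytosines was 28.7% ± 7.52 in 3 air females and 8.22% ± 6.09 in 5 e-cigarette females (SD; two-sided exact permutation p = 0.0179, the smallest that 56 splits can give). In males the same stretch stood at 19.7% ± 5.42 in air and 14.7% ± 9.11 in e-cigarette animals (n = 5 per group; two-sided exact permutation p = 0.325). The e-cigarette males were split by cluster. Males 4 and 5 stood at 6.92% and 3.31%, beside females 4 and 5 of their cluster at 3.94% and 4.13%. Males 1, 2 and 3 stood at 20.6%, 24.4% and 18.1%, within the 12.9% to 26.4% of the air males. In their cluster, females 1 and 3 stood at 13.7% and 15.99%, but female 2 at 3.40%. The group means therefore do not show a loss limited to females. Between 11910023 and 11911779 of chromosome 1, 84 called cytosines lay in a stretch with a mean coverage of 349 to 1183 reads per library, far above the median of 17 to 20. Its level was 68.1% ± 1.26 in air females and 46.5% ± 14.7 in e-cigarette females (two-sided exact permutation p = 0.0536, n = 3 and 5), and 38.6% ± 20.8 and 38.4% ± 11.4 in males (p = 1), with single libraries between 13.5% and 68.9%. The regions were found from the female calls, so their female p-values are not independent evidence.

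The clusters found from CpG methylation may mark litters, which is a hypothesis, since the labels name no litter. It was tested on RNA, which had no part in finding them. Among animals of the same exposure, deviations from the group mean correlated at a mean of 0.0470 over 19 male and female pairs of the same cluster and -0.0415 over 21 pairs of different clusters. The difference of 0.0885 had an exact one-sided permutation p of 0.00333, the smallest that the 300 permutations can give. The correlation is small, and shared handling of the animals within a cluster was not tested.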
